A study of Zea mays with 32 samples.

How the data were processed

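Source leaf laminae of the maize lines A188 and B73 were measured on Agilent single-channel arrays after growth in a chamber on nutrient-poor peat watered with 15 or 0.15 mM nitrate. The labels name 8 groups of 4 biological replicates, which are 2 lines, 2 supplies and 2 harvests, and 32 arrays in all. Day 20 arrays come from the fifth leaf and day 30 arrays from the sixth, so day and leaf number change together. Potassium was balanced with chloride salt, so chloride supply also differed between the nitrate supplies, and no comparison here separates the 2 ions. RNA came from frozen leaf tissue harvested before midday.

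The deposited scanner files hold intensity values for each spot in arbitrary scanner units, per the file headers, written by Agilent Feature Extraction 9.5.3.1. The deposited series matrix holds log2 ratios to the median of each probe over the arrays. These ratios could be remade from the scanner values (correlation 1, largest difference 0.0024, 41780 probes present among 41838 matrix rows), with column medians from -0.116 to 0.17. The scanner's processed signal was taken to log2 and the array's 75th percentile over non-control probes was subtracted. That percentile ran from 537.7 to 1101 intensity units. Between 63.3 and 79.9 percent of probes per array were well above background by the scanner's own test. Spots that the scanner marked as non-uniform (1209 spots, 4 to 137 per array) were set to missing. The plan had not named this step, and an alternative kept them. No spot carried the scanner's population outlier mark, and 41 spots were saturated, 23 of them on B73 low nitrate day 20 replicate 2.

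Probes well above background on at least 3 of the 4 arrays of at least 1 group were tested (33181 of 41780). Probe names are the best protein hits deposited with the array, which was designed on an early maize assembly. Of the 41780 probes, 12306 carried a descriptive name and 29474 did not, and 2964 matched a RefSeq protein in the reference table of the current B73 assembly, 120 of them with a gene symbol. No positions are given, and differences in sequence between the lines under a probe were not examined. A gene is a distinct best-hit accession (33984 among all probes, 27425 tested), represented by its brightest probe in list tests and correlations. Another 5756 tested probes belonged to 4398 genes with several probes. Where both the brightest and another probe were called, they went in opposite directions in 6 of 282 cases for A188 day 20, 2 of 248 for A188 day 30, 2 of 139 for B73 day 20, 24 of 520 for B73 day 30 and 79 of 1128 for the mean of the 4 contrasts.

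One linear model with a mean per group was fitted to all 32 arrays with limma 3.58.1 (lmFit and eBayes), and p was adjusted by Benjamini-Hochberg over the probes tested, with 0.05 as the threshold. Low minus high nitrate was tested in each line and day and as the mean of those 4 contrasts. The lines (B73 minus A188) and days (30 minus 20) were compared at high nitrate. A line by nitrate value is the low nitrate change in B73 minus that in A188, and a day by nitrate value is the change at day 30 minus that at day 20. The samples, the model, the 35 gene lists and the first alternatives were fixed before the data were examined. Lists were drawn up as name patterns, and some unrelated names were left out after the descriptions had been read. The lists for guard cells (0 genes measured), nitrogen signalling (2) and root tissue (1) were too small, which left 32 lists and 160 tests. Each list was compared with all other genes by limma's camera with the correlation between members estimated, and p was adjusted over the 160 tests. A count adjusted over the list alone applies Benjamini-Hochberg to the list's members only. limma's fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, was run as an alternative.

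Named genes were chosen by rule among probes with a descriptive name, and 119 were named. The first rule took the 4 largest rises and 4 largest falls of each nitrate contrast among probes with adjusted p under 0.05, with the 4 arrays of one group all above those of the other, and well above background on all 4 arrays of the higher group. The second took the members of each list with the smallest adjusted p in the mean contrast, passing or not, 4 for the nitrate and phosphate lists and 2 for the others. The third took 3 rises and 3 falls of each other contrast in the same way, without the condition on overlap for the interactions. Chosen in this way, the sizes of the named changes are the largest of many and so lean high. Where a probe was well above background on no array of a group, the change is given as a bound, or without a size where it is a mean of contrasts. The bound is the mean log2 value of the brighter group minus the mean, over the arrays of the dim group, of the higher of the array's lowest well-above-background signal and the probe's own signal. Where some arrays of the dimmer group detected the probe, their number is given. For an interaction with a group in which no array detected the probe, the results give no size, and the fitted value appears only among the flagged values, where it is said to be unmeasured.

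The arrays sat on 9 slides scanned on 6 days. For replicates 1 and 2 the nitrate supplies were on separate slides, and 15 arrays sat on slides that held both supplies for a line and day. Alternatives were normexp background correction (offset 50), quantile and median scaling, no filter and a stricter filter, the series matrix values, slide as a random or fixed block, only the slides with both supplies, the replicate number as a fixed block, only the arrays of the groups compared, trend and robust variances, 1 probe per gene, a 2-fold minimum, and each array left out in turn. Added after the data were examined were scan day as a fixed block, non-uniform spots kept, normexp without backgrounds that the scanner marked as outliers, list patterns without exclusions, and list tests and correlations with each array left out. Other splits of the same arrays were fitted to see how often they gave counts as large, with list p adjusted over the 32 lists of the contrast.

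The model was tested on simulated arrays with 50 changed probes at each of 1.5, 2, 3 and 4-fold. It called 6, 23, 41 and 47 of them for A188 day 20, 32, 49, 50 and 50 for the mean, 2, 13, 29 and 39 for the line by nitrate interaction at day 20, and 11, 27, 42 and 45 for the lines at day 20. Calls on unchanged probes made up 6 of 123, 11 of 192, 6 of 89 and 16 of 141 calls. The simulated noise was independent between arrays and held no slide effects, and 200 of 33181 probes were changed. The real arrays correlate within slides (0.522), so these rates need not hold for them. A recovery of 0.8 had first been asked for at 3 and 4-fold, which the interaction missed, and recovery is now reported without a mark. Most simulated changes of 1.5 and 2-fold in 1 line and day, and most interactions of that size, were thus missed, although some were called. Of 10 simulated lists with 40 genes each, the list shifted by 0.5 had adjusted p = 9.53e-06 and 1 of 9 unshifted lists was called as well. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, statmod 1.5.0 and version 1.17.8 of data.table.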

Results

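Source leaves of A188 and B73 grown on 15 or 0.15 mM nitrate were compared at day 20 (the fifth leaf) and day 30 (the sixth leaf), with 4 arrays per group. Changes are log2 values with their standard error from limma, and p values are adjusted over the probes tested unless a sentence says otherwise. Line, harvest and nitrate supply followed the first 3 principal components of the 32 arrays, which held 50.5, 17.7 and 7.82 percent of the variance. Line accounted for 99.8 percent of component 1, day for 84.9 percent of component 2 and nitrate for 87.9 percent of component 3. Of component 4 (4.39 percent) line, day and nitrate accounted for 0.00949, 1.19 and 3.99 percent, and slide accounted for 97.8 percent of its variation within groups. For components 1, 2 and 3 slide accounted for 77.4, 79.3 and 88.9 percent of the variation within groups. What share slides without any effect would give was not computed. Slides 1 to 4 held replicates 1 and 2 and slides 5 to 9 held replicates 3 and 4. An effect of slide therefore cannot be told apart from another difference between these sets of replicates. Within groups, arrays correlated at 0.9568 to 0.9937.

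**Figure D1:**
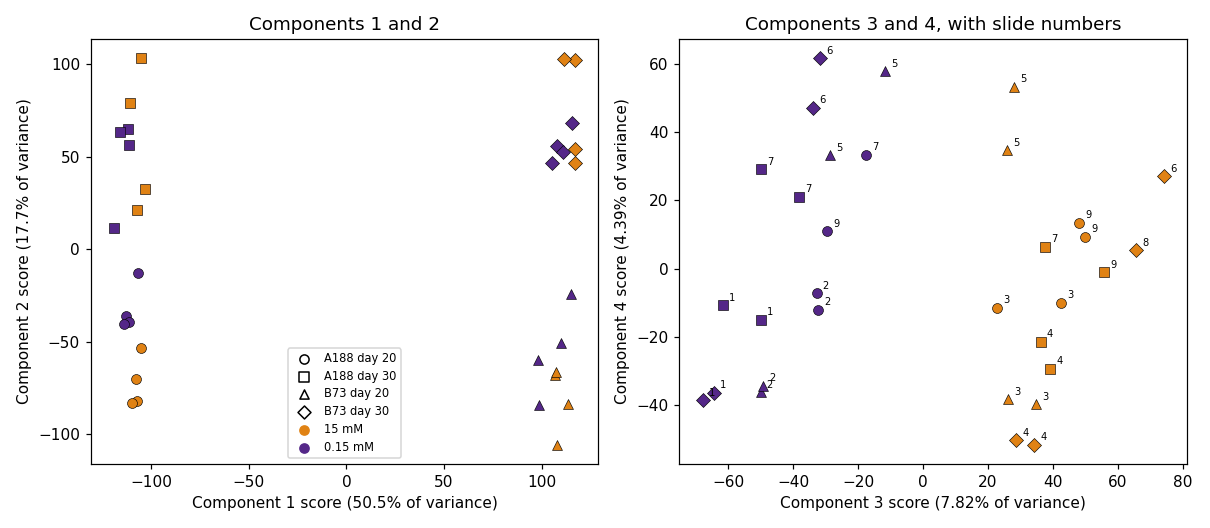
Scores of the 32 arrays on components 1 and 2 (left) and 3 and 4 (right), in score units with the percent of variance on each axis, shapes for line and day and colours for nitrate supply. Line separates on component 1 (50.5 percent) and nitrate on component 3 (7.82 percent). Component 4 (4.39 percent) parts slides 1 to 4, which held replicates 1 and 2, from slides 5 to 9, which held replicates 3 and 4. Slide numbers are printed beside the points on the right. Slide also accounts for 88.9 percent of the variation of component 3 within groups.

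Genes for the reduction of nitrate were lower at low nitrate in both lines, while nitrate transporters went different ways. Nitrate reductase, which makes nitrite from nitrate, fell in all 4 contrasts and by log2 -2.08 ± 0.10 in their mean (adjusted p = 3.64e-15). Siroheme uroporphyrinogen methyltransferase1, which makes the precursor of the siroheme in nitrite reductase, changed by -2.04 ± 0.10 (6.18e-15), and ferredoxin--nitrite reductase, which makes ammonium, by -1.55 ± 0.09 (3.24e-13). The high affinity nitrate transporter NRT2.5 changed by -0.90 ± 0.17 in the mean (0.000148) and by -2.45 ± 0.34 in B73 day 30 (1.12e-05), and did not pass in the other contrasts (-0.25, -0.81 and -0.11, each ± 0.34). Of 7 measured genes of nitrate uptake and assimilation, 5 fell, 1 rose and 1 did not pass, and the counts adjusted over the list alone were the same. The gene that rose is named only as a high affinity nitrate transporter (0.83). The list was lower than other genes with a median of -0.904 (adjusted p = 0.0145 with an estimated correlation), and also in each contrast: -0.94 in A188 day 20 (0.0344), -1.03 in A188 day 30 (0.0344), -0.30 in B73 day 20 (0.00715) and -2.08 in B73 day 30 (0.00715). The B73 day 20 median depends on the choice of the brightest probe, and was -1.03 with all probes of each gene.

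Genes that plants switch on when phosphate is short were lower at low nitrate, although phosphate supply was the same. Glycerophosphodiester phosphodiesterase, which frees phosphate from lipid breakdown products, changed by -3.79 ± 0.19 (1.49e-14). An SPX domain protein, of the family that senses phosphate status, changed by -3.22 ± 0.17 (2.32e-14). UDP-sulfoquinovose synthase, which feeds sulfolipid synthesis, changed by -1.91 ± 0.10 (3.82e-14) and inorganic phosphate transporter 1-7 by -1.30 ± 0.11 (5.21e-10). All 4 fell in every contrast. Of 15 measured genes of phosphate starvation and homeostasis, 10 fell, 1 rose and 4 did not pass (10 fell and 1 rose adjusted over the list alone). The list median was -1.30 (adjusted p = 0.0426 with an estimated correlation), and this call was lost in 8 of the 32 fits with 1 array left out.

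**Figure D2:**
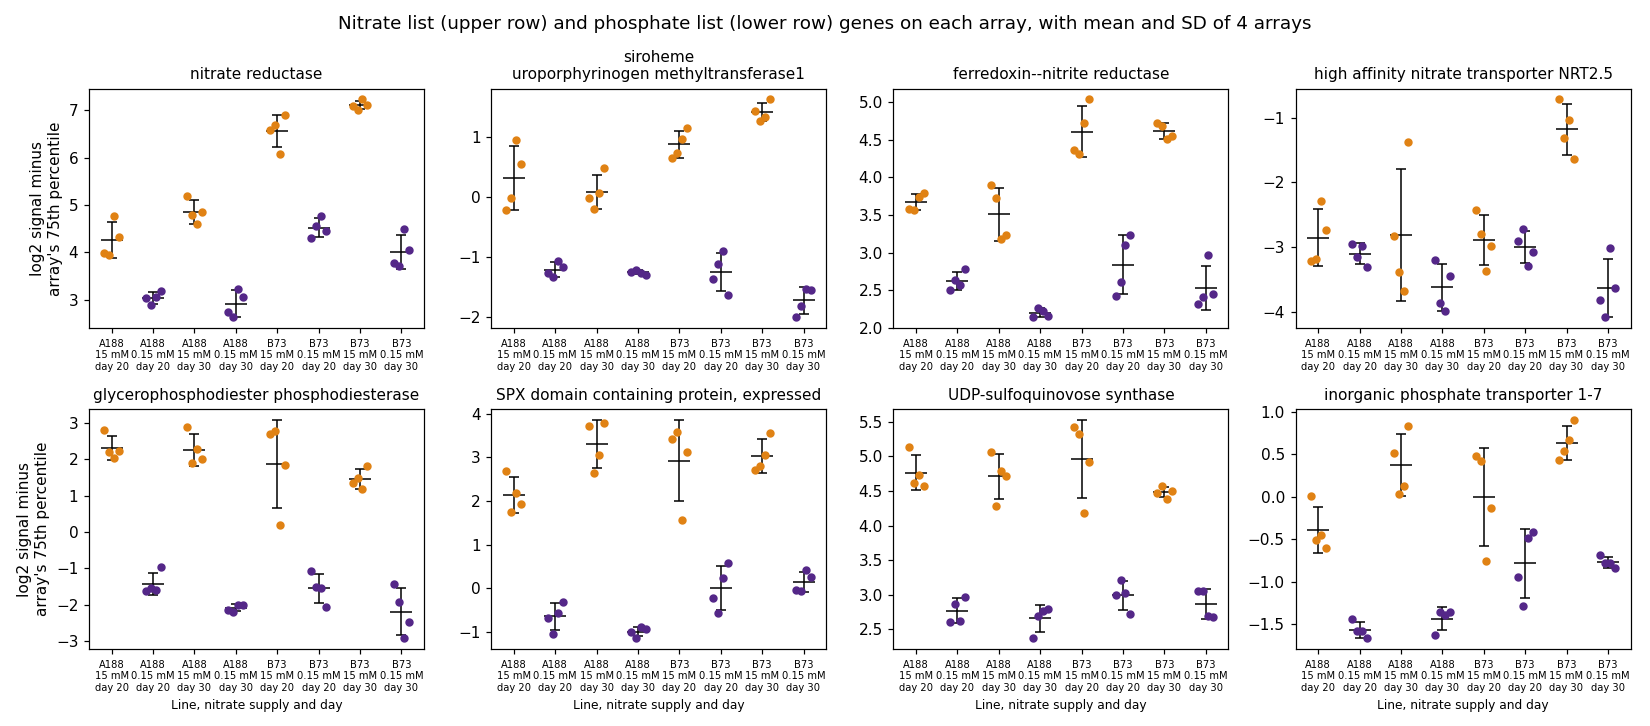
Signal of 4 nitrate list genes (upper panels) and 4 phosphate list genes (lower panels) on each array, as log2 signal minus the array's 75th percentile, by line, nitrate supply and day, with the mean and standard deviation of 4 arrays. Nitrate reductase is lower at 0.15 mM in each line and day, with a mean change of -2.08, and glycerophosphodiester phosphodiesterase with a mean change of -3.79.

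Over the mean of the 4 contrasts 11143 of 33181 probes were called (33.6 percent), 5529 higher and 5614 lower. Of those that changed at least 2-fold, 335 were higher and 818 lower. In at least 1 single contrast 9793 probes were called, of which 539 were called in all 4, 127 of them higher and 411 lower throughout, and 150 went in opposite directions in 2 contrasts. Overlaps between contrasts that share no array were larger than independent draws would give, though the lines shared slides for replicates 1 and 2 of each supply, so slide effects enter both, and in A188 slides 7 and 9 held arrays of both days. The lines shared 440 higher (43 if independent) and 695 lower probes (63) at day 20, and 812 (119) and 1218 (195) at day 30. The days shared 379 (67) and 753 (120) in A188, and 343 (76) and 704 (102) in B73. Across 27425 genes, which are not independent replicates, the low nitrate changes of the lines correlated with Pearson r 0.65 and Spearman rho 0.602 at day 20 and 0.644 and 0.614 at day 30. Between days the changes correlated at 0.544 and 0.39 in A188 and at 0.454 and 0.338 in B73. When only slides with both supplies were used, r was 0.469 and 0.494 between lines and 0.437 and 0.114 between days. That fit had no term for slide, so the A188 contrasts still mixed slides 7 and 9, and B73 high nitrate day 30 kept 1 array. How the calls divide into higher and lower depends on the scaling: 49.6 percent of the mean's calls were higher here, 56.5 percent with quantile normalization and 42.8 percent with normexp background correction. With normexp 3513 probes were called in the mean. When backgrounds marked by the scanner were left out, this and most other normexp counts given below came within 1.5 times of the main ones. Among 100 fits with nitrate labels permuted within each line and day, the real one included, 1 gave a count as large (highest other 46).

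**Figure D3:**
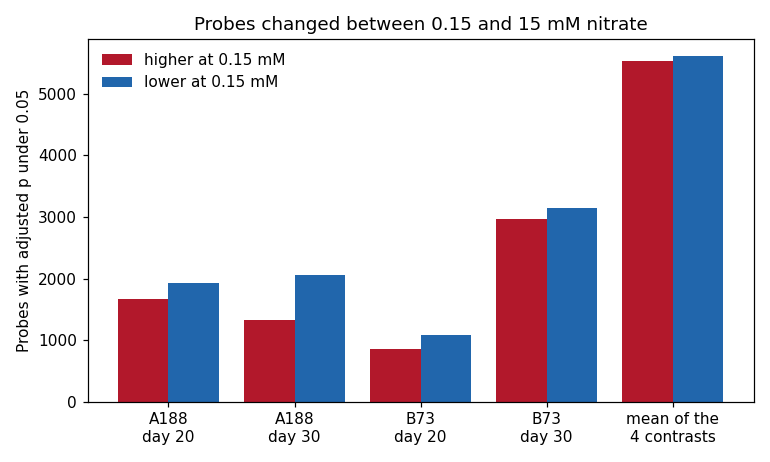
Bars give the number of probes with adjusted p under 0.05 between 0.15 and 15 mM nitrate in each line and day and in the mean of the 4 contrasts, higher (red) and lower (blue) at 0.15 mM. The counts run from 1927 in B73 day 20 to 6098 in B73 day 30 and 11143 in the mean.

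Amino acid, sugar phosphate and glycolytic enzymes were also lower in the mean. Threonine synthase, the last enzyme of threonine synthesis, changed by -1.43 ± 0.10 (6.96e-12) and shikimate kinase, on the way to aromatic amino acids, by -1.21 ± 0.11 (3.69e-09). Of 36 genes of amino acid biosynthesis, 20 fell and 2 rose (the same adjusted over the list alone), with a median of -0.236 (adjusted p = 0.0349 with an estimated correlation, lost with quantile normalization at 0.0574 and in 1 of 32 fits with 1 array left out). This shift came from day 20, with medians of -0.471 in A188 and -0.418 in B73. At day 30 the medians were 0.0353 and -0.0583, and the list was not called (adjusted p = 0.913 and 0.441 with an estimated correlation). In the oxidative pentose phosphate pathway, which supplies NADPH, 6-phosphogluconate dehydrogenase changed by -2.23 ± 0.12 (3.33e-14) and 6-phosphogluconolactonase by -0.87 ± 0.07 (2.13e-10). Of its 11 genes, 6 fell and 1 rose, also adjusted over the list alone, with a median of -0.314 (0.0309). Enolase1 changed by -1.20 ± 0.08 (9.88e-12) and phosphoglycerate mutase by -0.80 ± 0.08 (2.07e-08). Of 21 genes of glycolysis and organic acid metabolism, 12 fell and 1 rose (the same adjusted over the list alone), with a median of -0.32 (adjusted p = 0.0426, lost with quantile normalization at 0.116 and in 8 of 32 fits with 1 array left out).

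No other list passed in the mean contrast, although single members did. Many genes of photosynthesis were lower in the mean. Cytochrome b559 alpha chain changed by -0.67 ± 0.09 (1.23e-06) and photosystem II 11 kD protein by -0.75 ± 0.11 (9.54e-06). Of 52 genes of the light reactions 28 fell and none rose (28 adjusted over the list alone), with adjusted p = 0.507 for the list. In A188 and B73 the list medians were -0.412 and -0.339 at day 20 and -0.171 and -0.233 at day 30. Within the slides with both supplies they were -0.669 and -0.258 at day 20, but 0.0229 and 0.153 at day 30. A lower list at day 30 was thus not seen within slides, which held a single high nitrate array each. Phosphoenolpyruvate carboxylase kinase 3, which activates the first carboxylase of C4 photosynthesis, changed by -1.49 ± 0.12 (2.16e-10) and pyruvate,orthophosphate dikinase, which regenerates its substrate, by -1.08 ± 0.10 (2.43e-09). Of 25 genes of the C4 and Calvin cycles, 14 fell and 3 rose (the same adjusted over the list alone, list adjusted p = 0.121). Delta-aminolevulinic acid dehydratase changed by -1.03 ± 0.11 (3.56e-08). Of 8 genes of chlorophyll and tetrapyrrole biosynthesis, 5 fell, siroheme uroporphyrinogen methyltransferase1 among them (6 adjusted over the list alone, list adjusted p = 0.254). Of 4 photorespiration genes, serine hydroxymethyltransferase fell (-0.49 ± 0.09, adjusted p = 0.000111) and 3 did not pass, among them serine--glyoxylate aminotransferase (0.35 ± 0.14, adjusted p = 0.055). Adjusted over the list alone 1 fell and 1 rose (list adjusted p = 0.936).

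Sugar metabolism genes named here were lower. Sucrose phosphate synthase1, which makes sucrose phosphate, changed by -1.38 ± 0.10 (1.57e-11) and beta-amylase, which degrades starch, by -1.21 ± 0.13 (4.92e-08). Of 46 genes of starch and sucrose metabolism, 16 fell and 4 rose (18 and 5 adjusted over the list alone, list adjusted p = 0.328). A trehalose-6-phosphate synthase/phosphatase changed by -1.54 ± 0.11 (2.89e-11) and trehalose-6-phosphate synthase by -1.58 ± 0.20 (7.02e-07). Trehalose metabolism and SnRK1 had 4 of 14 genes lower and 1 higher, also adjusted over the list alone (list adjusted p = 0.441). Of 4 genes of phloem and sugar export none passed, nor did any adjusted over the list alone (sucrose transporter 2 0.31 ± 0.14, adjusted p = 0.0856, tie-dyed 1 0.29 ± 0.13, adjusted p = 0.0983, list adjusted p = 0.768). Asparagine synthetase 4 changed by -3.04 ± 0.28 (2.68e-09) and alanine aminotransferase 2 by -1.77 ± 0.14 (1.66e-10). In ammonium assimilation 5 of 16 genes fell while 5 rose (the same adjusted over the list alone, list adjusted p = 0.823).

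Among mineral nutrient lists, sulfate transporter (-1.39 ± 0.11, adjusted p = 1.66e-10) and adenosine 5'-phosphosulfate reductase 2 (-1.04 ± 0.10, adjusted p = 1.1e-08) fell. The sulfate list had 5 of 20 genes lower and 3 higher, also adjusted over the list alone (list adjusted p = 0.482). A putative chloride channel changed by -1.24 ± 0.08 (5.55e-13) and a voltage-gated potassium channel beta subunit by 0.82 ± 0.08 (3.23e-09). Of 28 genes of potassium and chloride transport, 10 rose and 8 fell (11 and 8 adjusted over the list alone, list adjusted p = 0.96). Yellow stripe1, the transporter of iron bound to phytosiderophores, changed by -3.12 ± 0.52 (3.31e-05, well above background on 3 of 4 low nitrate arrays of A188 day 20 and B73 day 30) and metallothionein-like protein type 2 by 1.14 ± 0.25 (0.000746). The iron and metal list had 9 of 25 genes lower and 4 higher, also adjusted over the list alone (list adjusted p = 0.521). An aquaporin of the NIP type rose by 0.69 ± 0.07 (2.29e-08) and PIP1-6 changed by -0.80 ± 0.14 (4.41e-05). Of the aquaporins 5 of 22 were lower and 1 higher, also adjusted over the list alone (list adjusted p = 0.507).

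Defence and secondary metabolism lists held members of both directions. A DNA-binding protein similar to WRKY3 passed (8.36e-10), but no size is given, since it was well above background on no low nitrate array of B73 day 30 and on 1 of 4 in each line at day 20. Under normexp its A188 day 20 change turned to 0.43, though not when marked backgrounds were left out. Lipoxygenase, which oxidizes polyunsaturated fatty acids, changed by -1.61 ± 0.19 (1.94e-07). Of the jasmonate and defence genes 46 of 137 fell while 20 rose (49 and 22 adjusted over the list alone, list adjusted p = 0.579). Thioredoxin-like 5 changed by -1.18 ± 0.17 (4.6e-06) and glutathione S-transferase GSTU6 by 1.03 ± 0.15 (4.92e-06). The oxidative stress list had 39 of 136 genes lower and 16 higher (40 and 16 adjusted over the list alone, list adjusted p = 0.472). Dihydroflavonol-4-reductase (0.46 ± 0.07, adjusted p = 2.37e-05) and leucoanthocyanidin reductase (0.43 ± 0.07, adjusted p = 3.16e-05), both of the flavonoid pathway, rose. The flavonoid and anthocyanin list had 21 of 68 genes higher and 12 lower (23 and 13 adjusted over the list alone, list adjusted p = 0.624). Cinnamate-4-hydroxylase rose by 0.63 ± 0.08 (5.84e-07), and 4-coumarate--CoA ligase-like 1 changed by -0.60 ± 0.09 (4.04e-06). The hydroxylase changed by 1.30 and 1.13 in B73, while in A188 it did not pass (0.29 and -0.19), and no line by nitrate value is given for it. Phenylpropanoid genes were split, 6 of 24 higher and 6 lower (7 and 6 adjusted over the list alone, list adjusted p = 0.936). Zeaxanthin epoxidase (-0.53 ± 0.07, adjusted p = 8.87e-07) and dxr protein (-0.52 ± 0.08, adjusted p = 1.46e-05) fell. The terpenoid and carotenoid list had 8 of 30 genes lower and 3 higher (10 and 4 adjusted over the list alone, list adjusted p = 0.743).

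Growth and protein turnover lists were split as well. Cellulose synthase6 (0.79 ± 0.07, adjusted p = 3.87e-09) and a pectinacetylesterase family protein (0.68 ± 0.07, adjusted p = 1.32e-08) rose. The cell wall list had 27 of 126 genes higher and 24 lower (27 and 26 adjusted over the list alone, list adjusted p = 0.96). Auxin efflux carrier component 1c changed by -0.92 ± 0.09 (4.04e-09) and cytokinin-O-glucosyltransferase 2, which conjugates cytokinins, by 0.86 ± 0.10 (1.34e-07). The cytokinin and auxin list had 28 of 116 genes lower and 21 higher (28 and 22 adjusted over the list alone, list adjusted p = 0.926). Histone H3.2 rose (0.50 ± 0.08, adjusted p = 1.11e-05) and tubulin-specific chaperone A fell (-0.37 ± 0.07, adjusted p = 0.000281). Among genes of dividing cells 14 of 62 were higher and 5 lower (12 and 5 adjusted over the list alone, list adjusted p = 0.789). Chaperone protein dnaJ changed by -1.24 ± 0.13 (4.92e-08) and heat shock factor protein HSF30 by 0.61 ± 0.07 (1.67e-07). The folding list had 20 of 99 genes lower and 15 higher (20 and 16 adjusted over the list alone, list adjusted p = 0.96). Senescence-associated protein 5 (-1.20 ± 0.15, adjusted p = 8.26e-07) and senescence-associated protein DIN1 (-1.02 ± 0.13, adjusted p = 1.02e-06) fell and belonged to both the next lists. Of the senescence genes 7 of 26 fell and 5 rose (list adjusted p = 0.791), and 12 of 64 protein degradation genes fell and 11 rose (list adjusted p = 0.864), each with the same counts adjusted over the list alone.

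Ribosomal protein lists hardly moved in the mean. 60S ribosomal protein L23 (0.80 ± 0.18, adjusted p = 0.00114) and L18A (0.60 ± 0.16, adjusted p = 0.00481) rose, L23 being well above background on 1 to 4 arrays per group. L23 turned to -0.27 under normexp background correction, but not when marked backgrounds were left out. Of 110 cytosolic ribosomal protein genes, 4 rose and 3 fell (3 and 1 adjusted over the list alone, list adjusted p = 0.936). Plastid-specific 30S ribosomal protein 1 changed by -1.74 ± 0.18 (1.81e-08) and a putative ribosomal protein by -0.50 ± 0.09 (0.000131). The plastid list had 6 of 42 genes lower and 1 higher (4 and 1 adjusted over the list alone, list adjusted p = 0.864). Of 7 clock genes, EARLY flowering 4 fell (-0.26 ± 0.06, adjusted p = 0.00156) and 6, LHY among them (-0.13 ± 0.07, adjusted p = 0.132), did not pass, also adjusted over the list alone (list adjusted p = 0.579). None of 9 lipid and wax genes passed, nor did any adjusted over the list alone (lipid-transfer protein 2 -0.40 ± 0.17, adjusted p = 0.0704, omega-6 fatty acid desaturase -0.22 ± 0.14, adjusted p = 0.23, list adjusted p = 0.96).

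**Figure D4:**
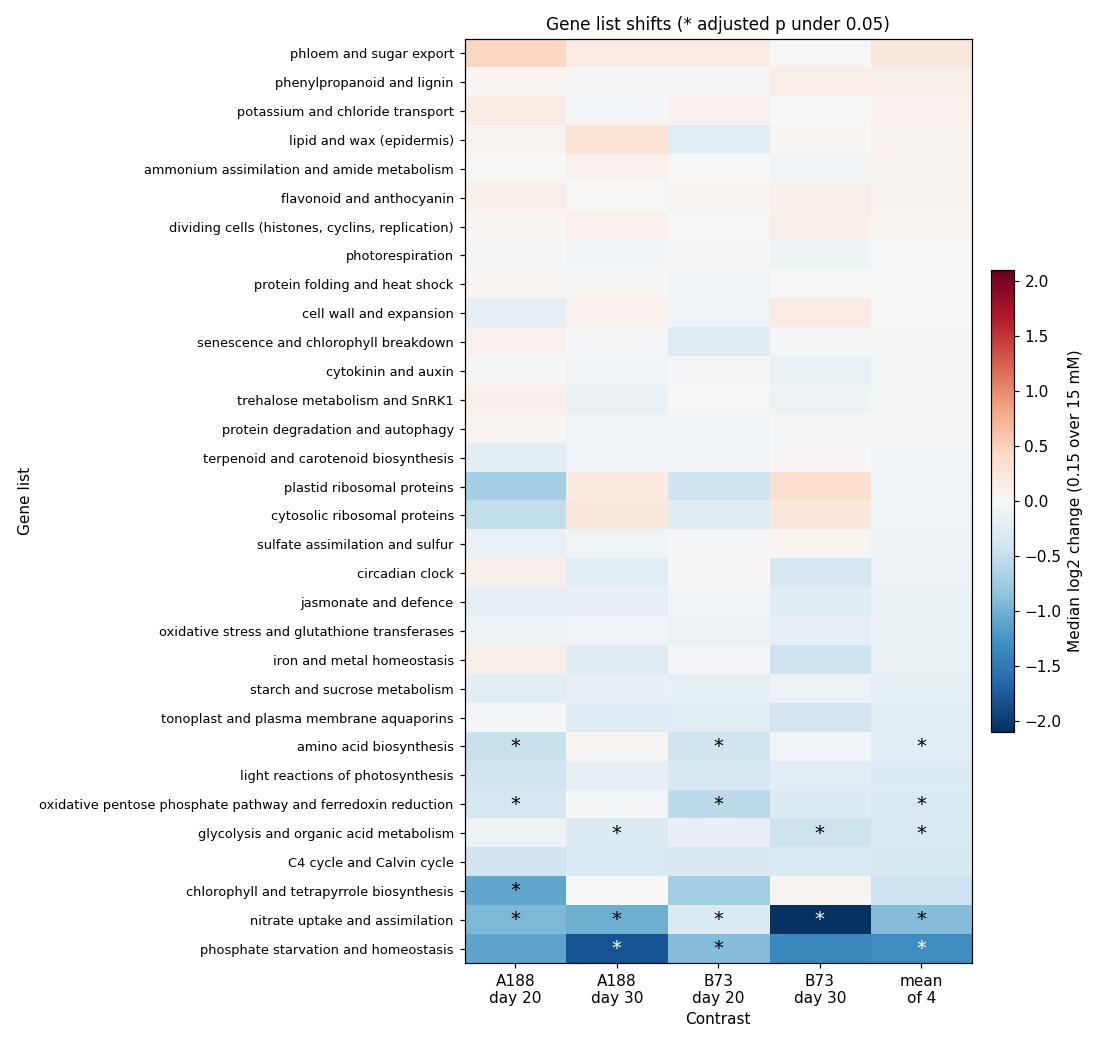
Median log2 change (0.15 over 15 mM nitrate) of 32 gene lists (vertical axis) in the 4 contrasts and their mean (horizontal axis), as a colour scale in log2 units, with asterisks at adjusted p under 0.05. The 18 asterisks all stand on lower lists, and the nitrate list carries 1 in each column, with medians from -0.30 to -2.08.

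With an estimated correlation 18 of the 160 list tests passed, all lower, and with a preset correlation of 0.01 these 18 and 35 others did. In the mean contrast the others were the light reactions (1.51e-06), C4 and Calvin cycles (0.000632), chlorophyll (0.000955), starch and sucrose (0.012), oxidative stress (0.0234), jasmonate and defence (0.0267) and aquaporins (0.0418). Median, mean and test differed in sign for 29 of the 160 tests, none of them called, and in the mean contrast for the ammonium, cell wall, folding, photorespiration, and potassium and chloride lists. None of the 160 tests passed with slide as a fixed block or on slides with both supplies alone. The medians of the 5 lists called in the mean stayed under 0 in both: -0.697 and -1.03 for nitrate, -1.18 and -1.28 for phosphate, -0.292 and -0.285 for amino acids, -0.384 and -0.337 for the pentose phosphate list and -0.179 and -0.241 for glycolysis. Why the calls were lost was not tested. The 5 lists called in the mean had adjusted p from 0.0656 to 0.13 with the replicate number as a block, with unchanged medians. The medians of the 18 called lists stayed under 0 with all 4 other scalings, which were looked at after the calls, but their size moved. The nitrate list in A188 day 20 went from -0.94 to -0.293 with normexp and -0.355 with normexp without marked backgrounds, and in A188 day 30 from -1.03 to -1.14 and -0.55.

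In A188 day 20, 3602 probes were called (10.9 percent), 1673 higher and 1929 lower. The genes named for each contrast are the largest changes among called probes with a descriptive name, no overlap between the arrays of the supplies and signal well above background on all 4 arrays of the brighter group, and probes outside this set can have larger changes. In this set a SANT/MYB protein (4.42 ± 0.48, adjusted p = 5.53e-07), anthocyaninless2 (3.87 ± 0.92, adjusted p = 0.00635, well above background on 2 of 4 high nitrate arrays), alliin lyase (3.30 ± 0.49, adjusted p = 5.01e-05) and an NAD(P)H-dependent oxidoreductase (3.21 ± 0.71, adjusted p = 0.00343) rose the most. Its largest falls were a putative MDR-like ABC transporter (at least 46.8-fold, adjusted p = 5.53e-07), a putative serine carboxypeptidase (at least 67.8-fold, adjusted p = 2.94e-06), hemoglobin 2 (-5.65 ± 0.32, adjusted p = 3.3e-12) and a phosphatase phospho1 (-4.83 ± 0.21, adjusted p = 1.15e-14). Called lists besides nitrate were amino acid biosynthesis (13 of 36 fell, 17 adjusted over the list alone, median -0.471, adjusted p = 0.00858), the oxidative pentose phosphate pathway (5 of 11 fell, 6 adjusted over the list alone, -0.368, adjusted p = 0.0224) and chlorophyll biosynthesis (6 of 8 fell, 7 adjusted over the list alone, -1.09, adjusted p = 0.0426, lost in 7 of 32 fits with 1 array left out). The phosphate list had 7 of 15 lower (median -1.10) and adjusted p = 0.149 with an estimated correlation.

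For A188 day 20 the nitrate supplies of replicates 1 and 2 lay on separate slides. Counts within a slide come from a fit with a mean per group and slide, whose spread is pooled over all arrays, since a supply can have a single array on a slide. That spread holds only differences between arrays of 1 group on 1 slide and leaves out those between slides. Such counts are therefore not comparable with those of the main fit. Within slide 9 (1 low and 2 high nitrate arrays) 4077 probes were called in this way. The fit of slides with both supplies alone gave 1042 and normexp background correction 514. Medians on slide 9 were -0.461 for amino acids, -1.44 for chlorophyll, -0.837 for nitrate and -0.646 for the pentose phosphate list. The contrast within scan day 2, from a like fit of all arrays with a mean per group and scan day, gave 4775 calls. Deviations from the group means correlated between replicates of the same number (0.249 to 0.307), and by up to 0.273 between different numbers. With the replicate number as a block 5056 probes were called, with adjusted p = 0.0383 for amino acids and 0.0478 for the pentose phosphate list, while the nitrate and chlorophyll lists (0.112 each) did not pass. The count was 2243 without low nitrate replicate 3, 2330 without low nitrate replicate 1, 2362 without high nitrate replicate 1 and 2377 without high nitrate replicate 4. Of 35 splits of the 8 arrays, 1 gave as many probes (highest other 27). For lists, with p adjusted over the 32 lists of the contrast in this test and not over all 160, 1 split gave as many (4, highest other 0).

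In A188 day 30, 3389 probes were called (10.2 percent), 1332 higher and 2057 lower. Among described probes without overlap between supplies, chosen as above, a receptor protein kinase similar to PERK1 (4.31 ± 0.43, adjusted p = 5.48e-08), a UBiQuitin family member (4.26 ± 0.55, adjusted p = 4.38e-06), a second SANT/MYB protein (3.74 ± 0.47, adjusted p = 2.72e-06) and anthocyanidin 5,3-O-glucosyltransferase, which adds glucose to anthocyanidins (3.01 ± 0.86, adjusted p = 0.0226, well above background on 3 of 4 high nitrate arrays), rose the most. The MDR-like ABC transporter (-9.28 ± 0.80, adjusted p = 4.71e-09, well above background on 1 of 4 low nitrate arrays), serine carboxypeptidase (at least 58.2-fold, adjusted p = 7.25e-07), a jasmonate-induced protein (-6.48 ± 0.73, adjusted p = 5.21e-07, on 2 of 4) and another phosphatase phospho1 (-6.27 ± 0.25, adjusted p = 3.84e-16) fell the most in this set. The phosphate list (9 of 15 fell and 1 rose, 9 and 2 adjusted over the list alone, median -1.82, adjusted p = 0.0344) and glycolysis (5 of 21 fell, 7 adjusted over the list alone, -0.295, adjusted p = 0.046, lost with quantile normalization at 0.116 and in 19 of 32 fits with 1 array left out) were lower. The glycolysis median was -0.31 under normexp, where the median of all genes was lower still at -0.372. The nitrate list had 3 of 7 lower (4 lower and 1 higher adjusted over the list alone), and its call was lost without high nitrate replicate 4 (0.0523).

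Within slide 7 (2 low and 1 high nitrate arrays) 2033 probes were called for A188 day 30, with the spread pooled over all arrays. With normexp the count was 1093. List medians on slide 7 were -1.79 for phosphate, -0.86 for nitrate and -0.185 for glycolysis. With the replicate number as a block 4763 probes were called, and the nitrate (0.115), phosphate and glycolysis lists (0.112 each) did not pass. Of 35 splits, 1 gave as many probes (highest other 1844, the split of replicates 1 and 2 from 3 and 4, which are on other slides) and 1 as many lists (2 when adjusted over the 32 lists of the contrast, highest other 0).

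In B73 day 20, 1927 probes were called (5.81 percent), 847 higher and 1080 lower. Among described probes without overlap between supplies, alliin lyase (3.89 ± 0.49, adjusted p = 6.1e-06), RING-H2 finger protein ATL3C (3.31 ± 0.26, adjusted p = 2.52e-09, well above background on 3 of 4 high nitrate arrays), a putative disease resistance protein (at least 3.58-fold, adjusted p = 4.23e-07) and salicylic acid-binding protein 2 (2.70 ± 0.57, adjusted p = 0.00362, on 2 of 4) rose the most. Serine carboxypeptidase (at least 40-fold, adjusted p = 4.71e-06), hemoglobin 2 (-5.31 ± 0.32, adjusted p = 2.31e-11), a putative ids-4 protein (-4.20 ± 0.40, adjusted p = 5.84e-08) and CBL-interacting protein kinase 15 (-3.79 ± 0.57, adjusted p = 7.9e-05, on 2 of 4 low nitrate arrays) fell the most in this set. Lower lists were amino acid biosynthesis (9 of 36 fell, 14 adjusted over the list alone, median -0.418, adjusted p = 0.00715), the pentose phosphate pathway (5 of 11 fell and 1 rose, also adjusted over the list alone, -0.555, adjusted p = 0.00858), nitrate (3 of 7 fell, also adjusted over the list alone) and phosphate (9 of 15 fell, also adjusted over the list alone, -0.903, adjusted p = 0.0344). The phosphate call was lost in 2 of 32 fits with 1 array left out, one of them without low nitrate replicate 2 (0.0611). Chlorophyll biosynthesis had 3 of 8 lower and adjusted p = 0.0529.

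The B73 day 20 count moved with the slides. Within slide 5 (2 arrays per supply) 6603 probes were called, and 3417 within scan day 2, both in fits of all arrays whose spread leaves out differences between slides. Normexp background correction gave 226. Medians on slide 5 were -0.643 for amino acids, -0.704 for the pentose phosphate list, -0.411 for nitrate and -0.273 for phosphate. Deviations of replicates of the same number correlated (0.165 to 0.35), and those of different numbers by up to 0.373. With the replicate number as a block 2832 probes were called, with adjusted p = 0.0275 for amino acids and 0.0383 for both the nitrate and the pentose phosphate list, while phosphate (0.112) did not pass. Slide as a fixed block gave 5769 probes, and the fit of these 8 arrays alone gave 486. Without low nitrate replicate 1 the count was 1236. Of 35 splits, 2 gave as many probes, a share over 0.05. The other was the split of replicates 1 and 2 from 3 and 4 (4572), which were on other slides, and so shows a structure of the arrays. Whether it comes from the slides or from another difference between these replicates cannot be told apart. Among the 8 splits that part all 4 replicate numbers the highest other count was 66, though 8 splits are too few for a share under 0.05. For lists 1 of 35 gave as many (5 when adjusted over the 32 lists of the contrast, highest other 3).

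In B73 day 30, 6098 probes were called (18.4 percent), 2960 higher and 3138 lower. Among described probes without overlap between supplies, the receptor protein kinase similar to PERK1 (3.96 ± 0.43, adjusted p = 3.07e-07, well above background on 2 of 4 high nitrate arrays), the second SANT/MYB protein (3.88 ± 0.47, adjusted p = 1.68e-06), a lipid binding protein (3.54 ± 0.99, adjusted p = 0.0129) and chalcone--flavonone isomerase, an early enzyme of flavonoid synthesis (3.35 ± 0.62, adjusted p = 0.000392, on 2 of 4), rose the most. AIR12 (-6.24 ± 0.62, adjusted p = 7.66e-08, on 2 of 4 low nitrate arrays), hemoglobin 2 (-5.41 ± 0.32, adjusted p = 5.74e-12, on 2 of 4), peroxidase 72 (-4.84 ± 0.51, adjusted p = 2.42e-07, on 1 of 4) and Ids3, a dioxygenase of phytosiderophore synthesis in barley (-4.82 ± 0.60, adjusted p = 2.79e-06, on 1 of 4), fell the most in this set. The nitrate list had 4 of 7 lower and 1 higher, also adjusted over the list alone. Glycolysis had 8 of 21 lower and 1 higher (9 and 1 adjusted over the list alone, median -0.444, adjusted p = 0.046, lost with quantile normalization at 0.128 and in 15 of 32 fits with 1 array left out). The phosphate list had 9 of 15 lower and 1 higher with a median of -1.35 (adjusted p = 0.0978 with an estimated correlation).

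Within slide 6 (2 low and 1 high nitrate arrays) 6670 probes were called for B73 day 30, again with the pooled spread. Medians there were -1.81 for nitrate, -0.30 for glycolysis and -1.48 for phosphate. Deviations of replicates of the same number correlated (0.167 to 0.36), and those of different numbers by up to 0.343. With the replicate number as a block 7811 probes were called, with adjusted p = 0.0478 for nitrate and 0.112 for glycolysis. The count was 3312 in the fit of these 8 arrays alone, 3287 on slides with both supplies and 1492 with normexp. Of 35 splits, 1 gave as many probes (highest other 3678, again the split of replicates 1 and 2 from 3 and 4) and 1 as many lists (1 when adjusted over the 32 lists of the contrast, highest other 0).

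The low nitrate change differed between the lines for 39 probes at day 20 (0.118 percent, 24 higher and 15 lower) and 232 at day 30 (0.699 percent, 157 and 75). At day 20 the named differences (B73 minus A188) were RALFL33, a peptide of the RALF family (2.31 ± 0.43, adjusted p = 0.0116), phosphatase phospho1 (1.84 ± 0.30, adjusted p = 0.00239), a protein similar to purple acid phosphatase (-3.17 ± 0.53, adjusted p = 0.00351), liguleless2, a transcription factor of the ligule region (-1.82 ± 0.30, adjusted p = 0.00247), and the inositol phosphatase CVP2 (-1.67 ± 0.30, adjusted p = 0.00918). RALFL33 changed by -1.17 ± 0.30 in A188 (0.0119) and 1.14 ± 0.30 in B73 (0.0205), but with normexp the A188 change turned to 0.30 and the difference was 0.10. With normexp without marked backgrounds the A188 change did not turn. Liguleless2 changed by 0.90 ± 0.21 (0.00517) and -0.92 ± 0.21 (0.00682). At day 30 a purple acid phosphatase (4.97 ± 0.72, adjusted p = 0.000271) had the lower change in A188. The other 5 named genes passed but had a group with no array well above background, so no size is given and a difference in response is not shown. These were the MDR-like ABC transporter (adjusted p = 0.00421) and the jasmonate-induced protein (0.0222), on no B73 low nitrate array of that day, and AIR12 (3.01e-05), Ids3 (0.00333) and peroxidase 72 (0.000505), on no A188 array of that day. The transporter's B73 fall at day 30 was at least 2.43-fold.

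Replicates 1 and 2 of both lines shared slides within a supply. Their difference, in the fit of all arrays with a mean per group and slide, called 438 probes at day 20 and 246 at day 30. Its spread leaves out differences between slides. The replicate number as a block gave 60 at day 20 and slide as a fixed block gave 287 and 1191. Normexp gave 9 and 20, and the fit of the compared arrays alone 121 at day 30. With normexp without marked backgrounds the day 30 count came within 1.5 times of the main one, and the day 20 count was above that range. Without B73 high nitrate replicate 3 the day 20 count was 79. Of 100 permutations of residuals, the real one included, 2 gave as many at day 20 (highest other 52) and 1 at day 30 (highest other 19).

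Between days the low nitrate change differed for 413 probes in A188 (1.24 percent, 231 higher and 182 lower) and 512 in B73 (1.54 percent, 276 and 236). In A188 the second SANT/MYB protein (2.79 ± 0.66, adjusted p = 0.0307), the alpha subunit of the RuBisCO subunit binding-protein, a chloroplast chaperonin (2.43 ± 0.49, adjusted p = 0.0147), and a protein kinase (2.43 ± 0.46, adjusted p = 0.013) had higher changes at day 30 (the sixth leaf). The chaperonin subunit went from -1.20 ± 0.35 (0.0243) to 1.23 ± 0.35 (0.0202), and the kinase from -1.09 ± 0.33 (0.0293) to 1.34 ± 0.33 (0.00694). Under normexp the kinase interaction turned to -0.39, but not when marked backgrounds were left out. A purple acid phosphatase (-3.42 ± 0.72, adjusted p = 0.0184) and a protein binding protein (-3.13 ± 0.79, adjusted p = 0.0428) had lower ones. The jasmonate-induced protein also passed (0.0237), but no low nitrate array of day 20 had it well above background, so a larger fall at day 20 would not have been seen and no difference is claimed. In B73 xyloglucan endotransglucosylase/hydrolase, which remodels cell walls (3.14 ± 0.69, adjusted p = 0.0223, well above background on 2 of 4 high nitrate arrays of day 30), and a protein listed as H0102C09.4 (3.13 ± 0.67, adjusted p = 0.02, on 3 of 4) had higher changes at day 30. A germin-like protein 1-4 also passed (0.016). It was well above background on no high nitrate array of day 30, so its rise there is a bound (at least 5.14-fold). AIR12 (-7.29 ± 0.88, adjusted p = 4.33e-05), peroxidase 72 (-4.50 ± 0.73, adjusted p = 0.00248) and a clathrin assembly protein (-4.38 ± 0.72, adjusted p = 0.00334) had lower fitted ones. At day 20 AIR12 was well above background on 1 of 4 high and 2 of 4 low nitrate arrays and peroxidase 72 on 3 and 2, so their sizes are rough. A fall of AIR12 at day 20 could hardly have been seen, so no difference in response between days is claimed for it.

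These interaction counts moved a great deal with single arrays and with the slides. The A188 count ran from 154 (without high nitrate day 20 replicate 1) to 590 over the 16 arrays and moved by more than 1.5 times for 10 of them, and the B73 count from 163 (without high nitrate day 30 replicate 4) to 784 (without low nitrate day 20 replicate 2), moving for 11. The replicate number as a block gave 877 and 1064, and slides with both supplies 52 and 2098. Normexp gave 6 and 7, and the fit of the compared arrays alone 919 and 36. With normexp without marked backgrounds the B73 count came within 1.5 times of the main one, and the A188 count was above that range. Of 100 permutations, the real one included, 1 gave as many in each line (highest others 11 and 362).

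At high nitrate 12738 probes differed between the lines at day 20 (38.4 percent, 6021 higher and 6717 lower in B73) and 12430 at day 30 (37.5 percent, 6032 and 6398). At day 20 an alanine aminotransferase 2 probe (11.29 ± 0.78, adjusted p = 1.79e-12), a leaf senescence related protein (9.65 ± 0.51, adjusted p = 7.4e-15) and an anthocyanidin 5,3-O-glucosyltransferase (9.08 ± 0.46, adjusted p = 2.98e-15) were higher in B73, each well above background on 1 of 4 A188 arrays. Glutathione S-transferase GST 18 (at least 98.4-fold, adjusted p = 1.29e-11), an isoflavone reductase (-8.50 ± 0.63, adjusted p = 9.64e-12, on 1 of 4 B73 arrays) and the cellulose synthase-like CslF7 (-8.47 ± 0.85, adjusted p = 4.02e-09, on 2 of 4) were lower in B73. At day 30 alanine aminotransferase 2 (at least 905-fold, adjusted p = 3.18e-12), the leaf senescence related protein (at least 402-fold, adjusted p = 2.93e-15) and a thioredoxin H-type (9.18 ± 0.39, adjusted p = 4.64e-17) were higher in B73. CslF7 (-9.77 ± 0.85, adjusted p = 2.38e-10, on 1 of 4), the isoflavone reductase (at least 427-fold, adjusted p = 9.22e-13) and a brassinosteroid LRR receptor kinase (at least 62.9-fold, adjusted p = 5.09e-13) were lower. A probe that binds the sequence of 1 line better would give such a difference as well, and the sequences were not compared.

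Within slide 3 (2 arrays per line) 12876 probes differed between the lines at day 20, and within slide 4 12604 differed at day 30. Normexp gave 3455 and 4763. Deviations of replicates of the same number correlated at day 30 (0.121 to 0.357), and those of different numbers by up to 0.319. With the replicate number as a block 13831 probes were called there and 14355 at day 20. Of 35 splits, 1 gave as many at each day (highest others 575 and 2903). The latter was the split of replicates 1 and 2, all on slide 4, from replicates 3 and 4, which were spread over other slides.

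Between day 20 and day 30, and so between leaves 5 and 6, 12200 probes differed at high nitrate in A188 (36.8 percent, 5840 higher and 6360 lower at day 30) and 13670 in B73 (41.2 percent, 6973 and 6697). Of those that differed at least 2-fold, 1800 were higher and 3125 lower at day 30 in A188, and 2253 and 3608 in B73. In A188 ZCN12, a maize gene of the FT family that includes florigen (at least 34.7-fold, adjusted p = 4.06e-08), the jasmonate-induced protein (5.80 ± 0.73, adjusted p = 1.93e-06) and a DNA binding protein (5.64 ± 0.73, adjusted p = 2.45e-06) were higher at day 30. Glucan endo-1,3-beta-glucosidase (-5.91 ± 0.73, adjusted p = 1.33e-06), an insoluble beta-fructofuranosidase, which cleaves sucrose in the cell wall (-5.47 ± 0.95, adjusted p = 7.71e-05), and the ABA induced protein PM 19 (-4.75 ± 0.63, adjusted p = 3.56e-06) were lower, each well above background on 1 of 4 arrays at day 30. In B73 AIR12 (6.77 ± 0.62, adjusted p = 1.43e-08, on 1 of 4 day 20 arrays), terpene synthase 4 (6.36 ± 0.56, adjusted p = 7.24e-09, on 1 of 4) and a protein similar to an aluminum-activated malate transporter (5.98 ± 0.62, adjusted p = 5.45e-08, on 2 of 4) were higher at day 30. A gene named meiosis 5 (-7.30 ± 0.99, adjusted p = 2.12e-06, on 2 of 4 day 30 arrays), a peptidyl-prolyl cis-trans isomerase (at least 19.7-fold, adjusted p = 1.73e-06) and a polygalacturonase, which cleaves pectin (-6.17 ± 0.52, adjusted p = 5.02e-09, on 2 of 4), were lower.

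Within slide 9 (1 day 30 and 2 day 20 arrays) the probes called between days in A188 had a median change of 1.04 in the direction of their call. With all arrays, those of slide 9 included, it was 0.874. In the fit of all arrays with a mean per group and scan day, scan day 2 gave 10319 probes in A188 and 9576 in B73. No slide held both days of B73 at high nitrate, and scan day 3 held only 1 of its day 30 arrays. The replicate number as a block gave 14035 in A188 and 15350 in B73, and normexp 2961 and 5179. Of 35 splits, 1 gave as many in each line (highest others 1342 and 1933).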

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

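The splits and the tests between slides were written down before their own results were seen, though after the counts they bear on, and the scan day values were added later.

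In 43 of 950 groups of 4 arrays (4.53 percent), 1 array of a named gene lay far from the other 3. The ratio printed is Dixon's, the gap to the nearest array over the range, and chance alone gives about 1 such group in 20. In A188 low nitrate day 20 there were 11: anthocyaninless2 (0.854), NAD(P)H-dependent oxidoreductase (0.892), the PERK1-like kinase (0.841), dihydroflavonol-4-reductase (0.911), leucoanthocyanidin reductase (0.871) and glycerophosphodiester phosphodiesterase (0.876). Others were plastid-specific 30S ribosomal protein 1 (0.92), aquaporin NIP (0.886), CslF7 (0.832) and thioredoxin H-type (0.867). The anthocyanidin 5,3-O-glucosyltransferase of the line comparison was among them too (0.884). In A188 low nitrate day 30 there were 11 as well: the MDR-like ABC transporter (0.864), serine carboxypeptidase (0.896), the PERK1-like kinase (0.843), CBL-interacting protein kinase 15 (0.878) and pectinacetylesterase (0.882). Others were delta-aminolevulinic acid dehydratase (0.943), 60S ribosomal protein L18A (0.905), photosystem II 11 kD protein (0.863), inorganic phosphate transporter 1-7 (0.855), germin-like protein 1-4 (0.896) and the leaf senescence related protein (0.883). A188 high nitrate day 20 had 3: metallothionein-like protein type 2 (0.841), aquaporin NIP (0.841) and trehalose-6-phosphate synthase/phosphatase (0.866). A188 high nitrate day 30 had 5: serine carboxypeptidase (0.942), peroxidase 72 (0.859), threonine synthase (0.842), sucrose phosphate synthase1 (0.854) and germin-like protein 1-4 (0.912).

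B73 low nitrate day 20 had 4 such genes: hemoglobin 2 (0.928), Ids3 (0.854), serine--glyoxylate aminotransferase (0.904) and the brassinosteroid LRR receptor kinase (0.858). B73 low nitrate day 30 had 5: auxin efflux carrier 1c (0.834), cytochrome b559 alpha chain (0.949), senescence-associated protein 5 (0.831), sucrose phosphate synthase1 (0.833) and RALFL33 (0.92). B73 high nitrate day 30 had 4: ATL3C (0.917), cytokinin-O-glucosyltransferase 2 (0.831), sucrose phosphate synthase1 (0.844) and the anthocyanidin glucosyltransferase (0.904), and B73 high nitrate day 20 had 0. Of 30 array measures and groups looked at in the same way, 4 had such an array, all in the number of saturated spots: A188 high nitrate day 30 (ratio 1), A188 low nitrate day 30 (1), B73 low nitrate day 20 (0.957) and B73 low nitrate day 30 (1).

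The low nitrate change differed between lines or days, by the interaction test, for 39 probes at day 20, 232 at day 30, 413 in A188 and 512 in B73. Named values between lines at day 20 were RALFL33 2.310, phosphatase phospho1 1.842, purple acid phosphatase-like -3.174, liguleless2 -1.824 and CVP2 -1.671. At day 30 the line values were the MDR-like ABC transporter 6.195, purple acid phosphatase 4.974, jasmonate-induced protein 4.725, AIR12 -6.867, Ids3 -4.774 and peroxidase 72 -4.748. Between days in A188 the values were the second SANT/MYB protein 2.794, the RuBisCO binding-protein alpha subunit 2.432, the protein kinase 2.429, jasmonate-induced protein -4.645, purple acid phosphatase -3.415 and protein binding protein -3.129. B73 gave germin-like protein 1-4 3.343, xyloglucan endotransglucosylase/hydrolase 3.141, H0102C09.4 3.128, AIR12 -7.293, peroxidase 72 -4.496 and the clathrin assembly protein -4.378. A group with no array well above background enters the MDR-like, jasmonate-induced, AIR12, Ids3 and peroxidase 72 values between lines, the jasmonate-induced value in A188 and the germin-like value in B73, so these fitted values are unmeasured as sizes. For AIR12 in B73 most high nitrate arrays of day 20 were not well above background, so no difference between days is claimed for it.

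Chance in how the arrays were grouped was tested on other splits of the same arrays, the real split counted among them. Of 35 splits 1 was as large for A188 day 20 (3602 probes, highest other 27), A188 day 30 (3389, 1844) and B73 day 30 (6098, 3678). The same held for the lines at day 20 (12738, 575) and day 30 (12430, 2903), and the days in A188 (12200, 1342) and B73 (13670, 1933). By these shares chance is excluded as the whole cause of these counts if the 8 arrays of a comparison can be exchanged freely. The splits took no account of slides. Those with 1844, 3678 and 2903 probes part replicates 1 and 2 from 3 and 4, which were on other slides. An effect of slides on these counts, or of another difference between these replicates, is therefore not excluded. B73 day 20 had 2 of 35 (1927, highest other 4572), so by the share of splits chance is not excluded there. The split with 4572 parts the same replicates, which points to a structure of the arrays. Within slide 5 and with the replicate block the counts were 6603 and 2832. The spread behind the slide 5 count leaves out differences between slides. In A188 day 20, B73 day 20, B73 day 30 and the lines at day 30, deviations of all replicates of the same number correlated. Those of different numbers reached 0.273, 0.373, 0.343 and 0.319 there. For 24 of 32 arrays the best match among the 4 at the other supply had the same number, against 1 in 4 if numbers did not matter. This goes with paired numbers, but different numbers also correlated, so whether the numbers are pairs stays open. Among the 8 splits there that part all 4 replicate numbers the highest other counts were 1, 66, 13 and 13, though 8 splits are too few for a share under 0.05. Lists, adjusted here over the 32 lists of a contrast and so with other counts than over all 160 tests, gave 1 of 35 for A188 day 20 (4 called, highest other 0), A188 day 30 (2, 0), B73 day 20 (5, 3) and B73 day 30 (1, 0). Of 100 permutations 1 was as large for the mean (11143, 46), 2 for the line interaction at day 20 (39, highest other 52), and 1 each for that at day 30 (232, 19) and the day interactions in A188 (413, 11) and B73 (512, 362). For the mean and the interactions these shares exclude chance as the whole cause only if the arrays can be exchanged freely. The labels and residuals were permuted without regard to slides, within which arrays correlate (0.522). That condition is therefore in doubt, and an effect of slides on these counts is not excluded. On slides with both supplies the day 20 count between lines was 16.

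The low nitrate changes could come from slides, since the supplies of replicates 1 and 2 were on separate slides. Probes called from those arrays alone were read on the slide that held both supplies, where a slide effect predicts a signed median near 0 and a nitrate effect more than 0.5 of that between slides. For A188 day 20 the ratio was 0.903 (0.808 to 0.991 with an array left out) and for B73 day 30 0.596 (0.591 to 0.606), which argues against slides as the whole cause in both, though 1 supply had a single array on each slide, which could not be left out. For A188 day 30 (0.52, 0.476 to 0.57) and B73 day 20 (0.359, 0.262 to 0.463) the test could not decide, and part of the changes called between slides may be due to slides. What stays open as a hypothesis is the nitrate supply, or the chloride supply that changed with it.

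The lower phosphate list might also come from slides, in which case its median within the slide with both supplies would be 0 or higher. That median was -0.696 for A188 day 20, -1.79 for A188 day 30 and -1.48 for B73 day 30, and stayed under 0 with either array of the pair left out, which argues against slides there, again with a single array for the other supply. In B73 day 20 the median was -0.273 and ran from -0.784 to 0.0169 with an array left out, and since this range spans 0, slides and supply cannot be told apart for that contrast. Values of phosphate in the leaf were not among the data used here, so no biological explanation beyond the supply itself was tested.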

How the results depend on the processing

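The alternatives were fixed before the data were examined except scan day as a block, non-uniform spots kept, normexp without marked backgrounds, list patterns without exclusions, and the list tests and correlations with arrays left out, which were added afterwards. Where a count is not given for a setting it stayed within 1.5 times its value in the report, and all counts did so with quantile or median scaling, the stricter filter, series matrix values, trend and robust variances, 1 probe per gene and non-uniform spots kept. The cause of the moves below was not tested unless a sentence says so. Of 493 named gene values, 478 kept their call and sign under quantile scaling, 479 with the replicate block, 441 with slide as a fixed block, 382 on slides with both supplies alone and 330 under normexp, and of 5688 values with an array left out 5422 did and none reversed. Signal over background limits dim probes: 63.3 to 79.9 percent of probes per array were well above background.

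With normexp background correction the counts were 514 and 1093 (A188 day 20 and 30), 226 and 1492 (B73), 3513 (mean), 9 and 20 (line by nitrate), 6 and 7 (day by nitrate), 3455 and 4763 (lines) and 2961 and 5179 (days). On 14 arrays 1 to 16 spots, all marked by the scanner, had a local background more than 50 units above their signal, and the lower quartile of such an array rose to as much as -0.35 (-2.88 when marked backgrounds were replaced). Without such backgrounds 11 of 13 counts came within 1.5 times of those in the report. The others were 62 for line by nitrate at day 20 and 621 for day by nitrate in A188. Values of called genes turned under normexp for WRKY3-like (0.43), a putative ribosomal protein (0.092), senescence-associated protein 5 (0.087), RALFL33 (0.30) and the protein kinase (0.039) in A188 day 20. They also turned for the disease resistance protein (-0.435), 60S ribosomal protein L23 (-1.178) and the protein kinase (-0.347) in A188 day 30, for L23 in B73 day 30 (-0.128) and the mean (-0.271), and for the protein kinase between days in A188 (-0.386). With normexp without marked backgrounds none of these turned, and 464 of the 493 named gene values kept their call and sign. The share of calls that were higher also moved, for B73 day 20 from 44.0 percent to 11.9 with normexp and 30.4 with median scaling, and for A188 day 20 from 46.4 percent to 55.0 with quantile and 19.6 with normexp. With no filter day by nitrate in B73 gave 308 and the correlations between lines were 0.566 and 0.579.

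Slide as a random block gave 7420 (A188 day 20), 5105 (A188 day 30), 5228 (B73 day 20), 323 and 1214 (line by nitrate) and 3429 and 4212 (day by nitrate). Slide as a fixed block gave 7978 (A188 day 20), 5769 (B73 day 20), 287 and 1191 (line by nitrate), 4293 and 4917 (day by nitrate) and 0 list calls. Slides with both supplies alone, with 15 arrays, gave 1042 (A188 day 20), 3287 (B73 day 30), 7270 (mean), 16 (line by nitrate, day 20), 52 and 2098 (day by nitrate) and 0 list calls. Correlations there were 0.469 and 0.494 between lines and 0.437 and 0.114 between days, and dxr protein in B73 day 30 reversed to 0.046. That fit had no term for slide, and B73 high nitrate day 30 kept 1 array. The replicate number as a block gave 60 (line by nitrate, day 20), 877 and 1064 (day by nitrate) and 6 list calls. Scan day as a block gave 6648 (A188 day 20), 4369 (B73 day 20), 152 and 519 (line by nitrate) and 948 (day by nitrate, A188).

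A 2-fold minimum, which can only lower a count, gave 1177 and 1502 (A188), 826 and 2620 (B73), 1153 (mean), 6661 and 6929 (lines) and 4925 and 5861 (days). Fits of the compared arrays alone gave 5532 (A188 day 20), 486 (B73 day 20), 3312 (B73 day 30), 121 (line by nitrate, day 30) and 919 and 36 (day by nitrate). List calls were 53 with a preset correlation, 68 with fry, which compares a list with no other genes, 14 with quantile scaling and 12 to 22 with an array left out. With an array left out the counts ran from 2243 to 3332 in A188 day 20, 1236 to 2029 in B73 day 20, 31 to 79 for line by nitrate at day 20, 154 to 590 for day by nitrate in A188 and 163 to 784 in B73. The other counts stayed within 1.5 times.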

Other observations

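Whether lists differed between lines or days in their low nitrate change was tested after the results above were seen, with 128 tests of 32 lists and 4 interactions. Of these, 2 passed with an estimated correlation and 13 with a preset one. The nitrate list was lowered more in B73 than in A188 at day 30 (median difference -0.772, 2 of 7 members lower in the interaction and none higher, adjusted p = 0.028 with an estimated correlation). Amino acid biosynthesis in A188 had a higher change at day 30 than at day 20 (median difference 0.438, 4 of 36 members higher and none lower, adjusted p = 0.0365).

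Ribosomal protein genes had list medians of opposite sign at the 2 harvests. Plastid ribosomal proteins stood at -0.708 in A188 day 20 and 0.205 at day 30, and at -0.43 and 0.332 in B73. The differences between days were 0.844 in A188 and 0.69 in B73, each with adjusted p = 0.419 with an estimated correlation (2.28e-12 and 9.82e-11 with a preset one). Cytosolic ribosomal proteins differed by 0.784 in A188 (adjusted p = 0.564, preset 5.94e-22) and 0.495 in B73 (0.868, preset 1.22e-09). Members of these lists move together from array to array (correlations 0.295 and 0.537), and the difference did not pass when that was taken into account. Within the slides with both supplies the plastid list stood at -1.01, 0.391, -0.741 and 0.616 and the cytosolic list at -0.516, 0.228, -0.815 and -0.0853, in the order A188 day 20, A188 day 30, B73 day 20 and B73 day 30. The cytosolic list of B73 day 30 (0.24 with all arrays) thus had the other sign within its slide.

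Arrays from the same slide resembled one another: deviations from the group means correlated with a median of 0.224 over 32 pairs on a slide against -0.0305 over 416 other pairs. Arrays on a slide also came from the same set of replicates, so slide and set cannot be told apart here.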
